A study of Mus musculus with 12 samples.

How the data were processed

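Sorted bone marrow progenitors of 12 mouse samples were measured by RNA sequencing, and per the labels' protocols the libraries were made with a Lexogen 3' mRNA-seq kit, which reads 1 end of a transcript so that counts need no correction for gene length. The values are counts per gene symbol, not normalized, as deposited in a single table of 33924 genes. Per the submitters' processing notes, STAR 2.4, HTSeq 0.6.1, DESeq2 and the mouse build mm9 were named, without their order or role. The annotation, the strand setting and any use of molecular identifiers are not given in the sources used here, so reads of antisense, overlapping or near-identical genes could not be told apart and intervals or floors cover counting error only. The reference at hand was of build GRCm38, and no coordinates were used; 28577 of the 33924 symbols (84.2%) were found in it by name.

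Samples were grouped by the labels as old control, old het, young control and young het, with 3 samples each, and numbered 1 to 3 within a group, which pairs no samples. Total counts ranged from 645460 to 9645502, so that 3 counts stand for 0.311 CPM in the deepest and 4.65 CPM in the shallowest library. No pair of replicates agreed within sampling noise (chi-square per degree of freedom from 5.22 to 50.9). Of the 33924 genes 15075 had 0 counts in every sample.

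Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with TMM scaling. Genes had to pass filterByExpr with a minimum count of 10 and a minimum total of 15, which left 10604 genes. The 4 groups entered 1 fit without covariates and shared an estimate of the spread (biological coefficient of variation 0.535). The comparisons were het against control at each age, the difference between these effects, their average, and old against young within controls and within hets. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The SE of a gene's log2 change was derived as the absolute change divided by the square root of its F statistic. It is approximate, above all where a group had 0 counts. Levels are CPM against TMM-scaled totals, as mean ± SD of 3 samples; the totals are those of the tested genes, and for Wt1, which was not tested, those of all genes. A fold against a group with 0 counts was set against a floor of 3 counts over the group. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, on 32 lists of blood cell markers, cell cycle, stress, metabolic and regulatory genes with at least 5 tested members.

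The test, the samples, the lists, most alternatives and the rule for naming genes were fixed before the data were examined. Named genes were Wt1; in each comparison the 10 largest rises and falls among genes past the threshold with groups that did not overlap, or the 10 smallest p-values where fewer than 10 genes passed, predicted gene models giving place to the next; for each list up to 4 members by p where the list or a member passed and up to 2 otherwise; genes past the threshold at both ages or in the difference of effects; and the 5 genes with the largest share of counts. Not every gene so named is printed.

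Alternatives were DESeq2 1.42.0, limma-voom, other scaling and filters, the compared groups alone, leaving out the 20 most counted genes, Xist as a covariate, lists without shared members, and leaving out each library in turn. Added after seeing the data were the mitochondrial rRNA share as a covariate, a fit without mitochondrial, small RNA, sex-linked and predicted genes, and a fit without old control 1 and young control 3. The steps were tested on simulated counts with 200 changed genes. For young het against young control, edgeR recovered 0% of 2-fold, 53.7% of 4-fold and 60.6% of 8-fold changes, with 4 false calls over 10604 genes. For old het against old control it recovered 1.49%, 41.8% and 53.0%, with 2 false calls, and for old against young control 4.48%, 44.8% and 65.2%, with 6. For the difference of effects edgeR recovered 0%, 2.99% and 54.5%, with 1 false call. DESeq2 made 26 false calls in the young simulation. The simulated counts held no differences of sex, RNA class or single libraries, so their false calls can be fewer than those in the data.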

Results

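RNA was profiled by 3' tag sequencing in 12 libraries of mouse myeloid progenitors, sorted from bone marrow as live cells without lineage markers or Sca1 and with c-Kit. This gate holds progenitors of the granulocyte, monocyte, basophil, erythroid and megakaryocyte lines. The libraries fall into 4 groups of 3. Old mice with 1 floxed Wt1 allele are called old het here and old mice with intact Wt1 old control, and the young mice are named likewise. Wt1 encodes a zinc finger transcription factor that is mutated in part of acute myeloid leukaemias. The design sets het progenitors of each age against controls of that age. The labels tie "chronic" to every old and "acute" to every young sample without explaining either word, so an age difference cannot be told apart from that condition. They do not say whether replicates came from separate animals, and p-values therefore measure the spread between these samples only. The total count was 9645502, 3952356 and 2074955 in old controls 1 to 3, and 1264603, 2303346 and 1542185 in old hets 1 to 3. It was 1600995, 645460 and 1365425 in young controls 1 to 3, and 3113183, 6794892 and 5820076 in young hets 1 to 3.

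Wt1 itself was counted 1, 4 and 2 times in the old controls and 3, 2 and 4 times in the old hets. The young controls had 8, 4 and 6 counts and the young hets 7, 4 and 23. Mean levels were 0.636 ± 0.473 CPM (SD, n = 3) in old control, 1.94 ± 0.996 in old het, 5.79 ± 1.12 in young control and 2.28 ± 1.65 in young het. Wt1 was too low to enter the gene test. A 3' tag outside the deleted part is read from either allele, and the position of the tags relative to the deletion is not given in the sources used here, so these counts do not check the genotype labels.

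RNA classes differed between the groups. Mitochondrial rRNA took 2.07 ± 0.345% of counts (SD, n = 3) in old control, 3.64 ± 1.94% in old het, 5.87 ± 2.07% in young control and 3.17 ± 0.294% in young het. Mitochondrial mRNA took 4.65 ± 1.37% in young control and 1.61 ± 0.663% in young het. Small nuclear and nucleolar RNA took 0.613 ± 0.221% and 0.191 ± 0.00418%. All 3 shares were higher in every young control than in every young het and every old control, at a two-sided exact permutation p of 0.1 each (adjusted p = 0.2 over the shares and comparisons tested), the smallest p that 3 against 3 libraries can give. Xist, the RNA that coats the inactive X, lay between 616 and 2133 CPM and the Y-linked Ddx3y at 0 counts in old het 1, young control 3 and all 3 young hets, while the other 7 libraries carried Ddx3y. The labels number young control 3 as 18, next to the young hets at 19 to 21, and young controls 1 and 2 as 29 and 30. The old libraries are numbered 1 to 6. The labels name no batch, so a difference in preparation between these runs of numbers was not tested. The sex of the animals is not labelled, and the 3 young hets thus differ from young controls 1 and 2 in sex-linked RNA.

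**Figure D1:**
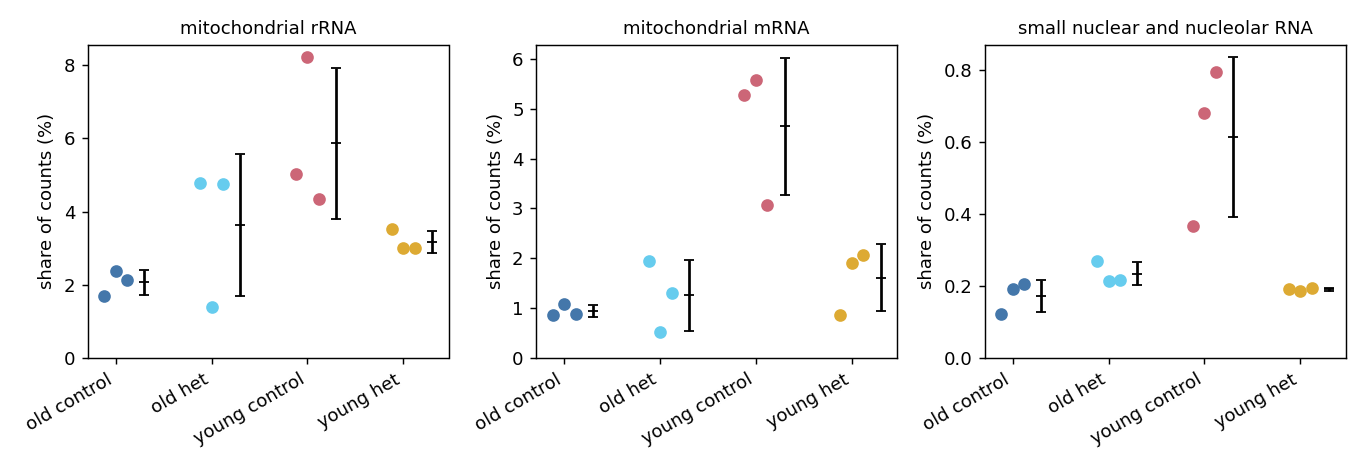
Share of counts (%) in 3 RNA classes for each library (points, 3 per group), with the group mean and SD beside them. Young controls have the highest mean shares, with 5.87 ± 2.07% mitochondrial rRNA. In this class old hets 1 and 3, at 4.78% and 4.75%, lie above young control 3, at 4.35%.

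The first principal component of log2 CPM held 28.0% of the variance and the second 15.8%. Young control 3 lay at 142 on the first component and every other library at 44.0 or below. Pearson's r over genes between replicates, which are values within pairs of libraries and not independent tests, ran from 0.758 to 0.865 among young controls, from 0.808 to 0.881 among young hets, from 0.849 to 0.901 among old hets and from 0.855 to 0.933 among old controls.

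**Figure D2:**
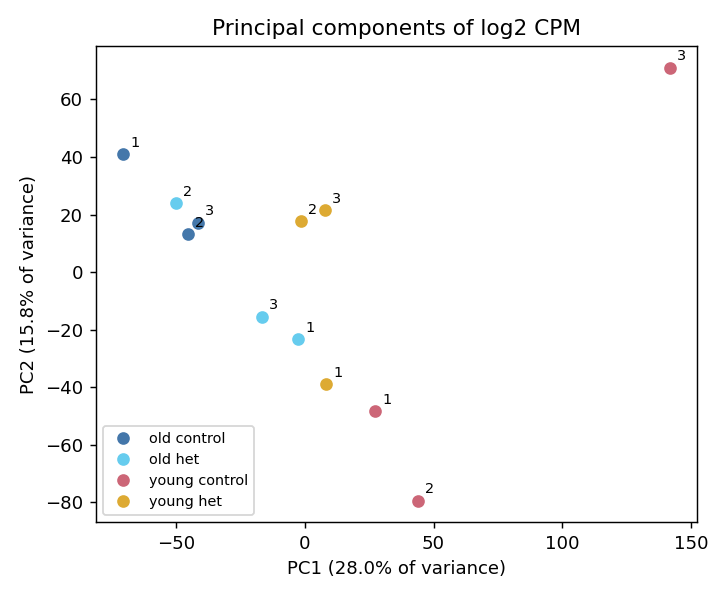
First and second principal components of log2 CPM (arbitrary units), 1 point per library, numbered by replicate and coloured by group. Young control 3 lies at 142 on the first component, apart from the rest.

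In young mice, 45 genes passed between het and control progenitors, with Gfi1 and Cebpd among the higher ones and U3 and Slbp among the lower. Gfi1, a repressor required for neutrophil differentiation, was 115 ± 26.3 CPM in young het and 14.8 ± 10.6 in young control (SD, n = 3 each), a log2 change of 2.85 (SE 0.62, adjusted p = 0.0477). Cebpd, a transcription factor of the C/EBP family active in myeloid maturation, was 25 ± 5.81 CPM in young het and had 0 counts in every young control, which makes it at least 26.8-fold higher, with the floor at 3 counts over the group (adjusted p = 0.0118). Counts of the small nucleolar RNA U3, needed for cleavage of the ribosomal RNA precursor, fell from 528 ± 72.4 to 54.6 ± 31.0 CPM, by 3.28 on the log2 scale (SE 0.41, adjusted p = 0.00128). The kit is one for mRNA, and whether counts of small nuclear, nucleolar or transfer RNA follow their levels was not tested. Slbp, which binds the stem-loop of histone mRNA in S phase, fell by 3.05 (SE 0.46, adjusted p = 0.00538). The groups did not overlap in any of these 4 genes.

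By edgeR's quasi-likelihood test, 45 of 10604 genes passed an adjusted p of 0.05, 19 higher and 26 lower in young het, and in 40 of them the 3 hets lay apart from the 3 controls. Over all tested genes the groups lay apart in 16.8%, where chance gives 10%. Among the higher genes were Cst7, an inhibitor of lysosomal proteases, at 2.68, and Idh1, the cytosolic isocitrate dehydrogenase, at 2.56 (SE 0.50). Nod1, a sensor of bacterial peptidoglycan, was at 3.42, Il21r, a cytokine receptor, at 2.42 and the adaptor Skap2 at 2.33. Ext2, a heparan sulfate polymerase, was at 2.46, Deb1 at 4.50, and the ribonuclease A family member Rnase12, with 0 counts in every young control, was at least 18.8-fold higher. Adjusted p-values of these 8 genes lay between 0.0385 and 0.0493. The lower genes included the mitochondrial tRNAs mt-Tq (-3.01), mt-Tm (-2.75) and mt-Tp (-2.53), the small nucleolar RNAs SNORD86 (-4.11), SNORA36 (-3.10) and Snord49b (-2.48), Cnot3 of the deadenylase complex (-2.42), Prkacb, a catalytic subunit of protein kinase A (-2.13), and the muscle kinase gene Speg (-2.88). Of the lower genes, 4 were mitochondrial tRNAs, 4 small nuclear or nucleolar RNAs and 4 Y-linked genes, the classes whose shares or sex pattern differed between these libraries.

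Of 32 gene lists, 5 passed camera in the young comparison. In the neutrophil primary granule list, 2 of 25 members rose, Gfi1 and Cst7, and 6 when adjusted over the list alone. Its members had a median log2 change of 0.81 (camera adjusted p = 1.22e-06, and adjusted p = 0.585 with an estimated correlation). Cebpa, a driver of granulocyte fate, was at 1.68 and the myeloid lectin Clec12a at 1.37, without passing over all genes (adjusted p = 0.133 and 0.115). In the basophil and mast cell list 1 of 16 members rose, and 2 when adjusted over the list alone, with a median of 0.69 (camera adjusted p = 0.0253, adjusted p = 0.585 with an estimated correlation). That member, Hdc, makes histamine and went from 162 ± 66.8 to 624 ± 44.3 CPM (log2 1.94, adjusted p = 0.0385). The basophil protease Prss34 was at 3.64 (adjusted p = 0.0701). None of 32 members of the unfolded protein response list passed over all genes and 2 passed when adjusted over the list alone, Ssr3 at 1.36 and Herpud1 at 1.57, with a list median of 0.41 (camera adjusted p = 0.0379, adjusted p = 0.815 with an estimated correlation). The basophil list did not pass without young control 1 (0.46, adjusted p = 0.103), young control 2 (0.62, adjusted p = 0.0991) or young het 3 (0.57, adjusted p = 0.0501), and its median was 2.22 without young control 3. The unfolded protein response list did not pass without young control 1 (0.47, adjusted p = 0.103), young control 2 (0.24, adjusted p = 0.108) or young het 1 (0.34, adjusted p = 0.319).

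The mitochondrial genome list was lower in young het, with a median of -1.67 over 10 members (camera adjusted p = 7.86e-10, adjusted p = 0.451 with an estimated correlation), and mitochondrial rRNA took 5.87 ± 2.07% of counts in young control. None of its members passed over all genes and 9 passed when adjusted over the list alone, among them mt-Nd4 (-1.77), mt-Nd6 (-2.10) and mt-Co1 (-1.64), subunits of respiratory complexes. In the sex-linked list, 4 of 5 members fell, also when adjusted over the list alone, with a median of -8.99, or -6.62 with genes at 0 set at the floor (camera adjusted p = 9.41e-05, adjusted p = 0.322 with an estimated correlation). Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in all 3 young hets and in young control 3, and against the mean of the controls they were at least 469-fold, 98.5-fold, 100.2-fold and 83.5-fold lower. Outside these lists Nfkbia, the inhibitor of NF-kB, fell by 2.11 (adjusted p = 0.0288), and Rpl6 was the member of 70 in the ribosomal protein list that passed (-1.95, adjusted p = 0.0394). The glycolysis and hypoxia list passed fry, a rotation test of whether members move 1 way (adjusted p = 0.0133, median 0.31), and not camera (adjusted p = 0.104, and 0.451 with an estimated correlation). In the list of published WT1 target genes, 1 of 23 members rose, Gfi1, and 2 when adjusted over the list alone, with a median of -0.01; Cdh1, the adhesion protein E-cadherin, was at 1.95 (adjusted p = 0.148).

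Each of the 6 young libraries moved the count of 45 by more than 1.5 times when left out, to 17, 1 and 157 without young control 1, 2 and 3 and to 13, 3 and 1 without young het 1, 2 and 3. It was 356 by DESeq2, 23 by limma-voom, 21 with Xist as a covariate, 2 with the mitochondrial rRNA share as a covariate and 241 without old control 1 and young control 3, the last 2 settings chosen after seeing the data. Genes higher in young het were 133 of the 356, 2 of the 23, 11 of the 21, 0 of the 2 and 117 of the 241. They were 2 of 13 with the compared groups alone and 16 of 47 with DESeq2 size factors. Without mitochondrial, small RNA, sex-linked and predicted genes, a setting also chosen after seeing the data, they were 2 of 7. With every library thinned to 645460 counts it was a median of 60 over 5 draws (53 to 82), a median of 37 of them among the 45. Without young control 1 or young control 2, 3 lists passed.

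**Figure D3:**
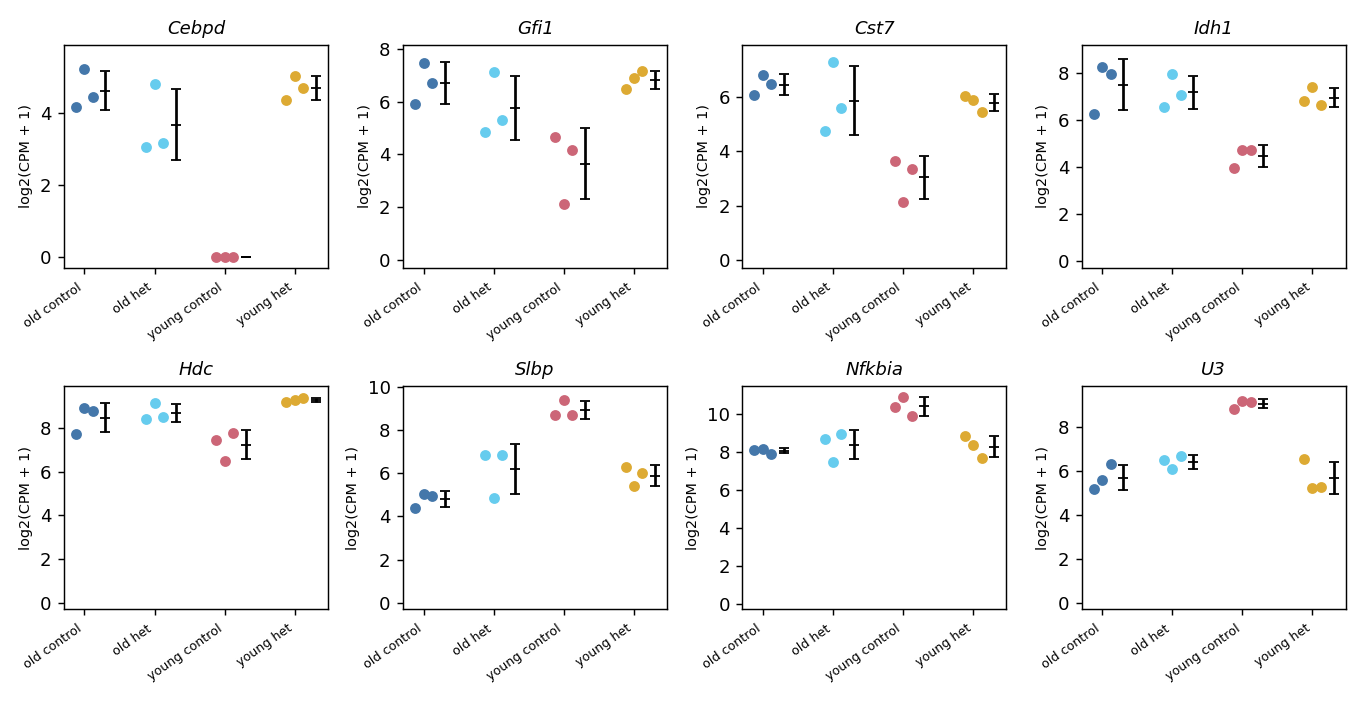
Expression of 8 genes as log2(CPM + 1), 1 point per library and 3 per group, with the group mean and SD beside them. Cebpd has 0 counts in the 3 young controls, and Slbp, Nfkbia and U3 are highest there.

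In old mice, no gene passed between het and control progenitors. Camera called 7 of 32 lists, 6 of them lower in old het (megakaryocyte, stem and multipotent progenitor, MHC class II, interferon response, oxidative phosphorylation and ribosomal protein) and the mitochondrial genome list higher, and none passed with an estimated correlation (adjusted p of 0.611 or more). Under all 10 splits of these 6 libraries into 3 against 3, the real one included, camera called 7 lists or more, up to 17. The number of lists called thus does not set het apart from control. F2r, the thrombin receptor, was 18.6 ± 9.85 CPM in old het and 92.2 ± 54.1 in old control (SD, n = 3 each), a log2 change of -2.34 (SE 0.55, adjusted p = 0.999). Sdcbp, the scaffold protein syntenin, was 206 ± 59.1 against 502 ± 39.9 (-1.28, SE 0.30, adjusted p = 0.999), and Psmb9, an interferon-induced subunit of the immunoproteasome, 36 ± 14.4 against 125 ± 28.2 (-1.79, SE 0.49, adjusted p = 0.999). The groups did not overlap in these 3 genes, and over all tested genes they lay apart in 11.1%, where chance gives 10%.

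Old het against old control gave 0 of 10604 genes with edgeR, 0 with DESeq2 and 0 with limma-voom, and 380 genes had an unadjusted edgeR p under 0.05. The 10 genes with the smallest unadjusted p, none of which passed, included Gar1 of the H/ACA small nucleolar ribonucleoproteins (-1.34), Fos, an immediate early transcription factor (-2.06), Rab38 (-2.25), Trim59 (-1.66), Slbp (1.63) and Xist (8.23), which was counted at 856 CPM in old het 1 and at 0 in old hets 2 and 3.

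All 22 tested members of the megakaryocyte list were lower in old het, with a median of -0.83 (camera adjusted p = 5.21e-05, adjusted p = 0.611 with an estimated correlation), and 1 passed when adjusted over the list alone. Besides F2r, the tetraspanin Cd9 was at -2.01 and Ctla2a at -2.12. The stem and multipotent progenitor list had a median of -0.95 over 25 members (camera adjusted p = 2.47e-04, adjusted p = 0.611 with an estimated correlation), with Txnip at -1.29, and the stem cell regulators Hlf at -2.04, Gata2 at -1.07 and Meis1 at -1.69. The dendritic cell and MHC class II list had a median of -1.38 over 14 members, 3 of them lower when adjusted over the list alone (camera adjusted p = 0.00421, adjusted p = 0.611 with an estimated correlation). Its members Cd74, the invariant chain, H2-Aa and H2-Eb1 were at -2.75, -3.03 and -3.62, and H2-Aa was 8.79 ± 7.43 CPM in old het and 74.6 ± 97.5 in old control. The interferon response list had a median of -0.58 over 42 members (camera adjusted p = 0.00487, adjusted p = 0.611 with an estimated correlation), with Ifi47 at -1.75 and Ly6e at -1.08. Without old control 1 none of these 4 lists passed (adjusted p of 0.0767 or more), and their medians in this order were -0.33, -0.03, -0.07 and -0.07, with Hlf at -0.28 and Meis1 at 0.25. Without old het 2 the MHC class II list (-0.77, adjusted p = 0.0765) and the interferon list (-0.72, adjusted p = 0.0765) did not pass, and the megakaryocyte median was -1.29.

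The oxidative phosphorylation list was lower by a median of 0.30 over 73 members and the ribosomal protein list by 0.25 over 70, each with 0 members past the threshold, also when adjusted over the list alone. Their camera adjusted p-values were 9.66e-04 and 0.00873, each with an adjusted p = 0.611 with an estimated correlation. Examples were Atp5g3 (-0.99) and Ndufa1 (-1.77) of the respiratory chain, and Rps2 (-1.26) and Rpl22 (-0.78) of the ribosome. The mitochondrial genome list was higher, at a median of 0.57 over 10 members (camera adjusted p = 0.00623, adjusted p = 0.644 with an estimated correlation), with the ribosomal RNAs mt-Rnr1 at 0.92 and mt-Rnr2 at 0.98. Mitochondrial rRNA was 4.78% and 4.75% of counts in old hets 1 and 3 and 1.40% in old het 2. Without old control 1, the deepest library, 4 lists passed. They were oxidative phosphorylation, ribosomal protein and, not called with all libraries, primary granule (adjusted p = 0.0130) and erythroid (adjusted p = 0.0219), each lower in old het. The mitochondrial genome list did not pass without old control 1 (0.47, adjusted p = 0.0767) or old het 1 (0.19, adjusted p = 0.826), and its median was 0.97 without old het 2. Oxidative phosphorylation did not pass without old control 3 (-0.15, adjusted p = 0.0517), and its median was -0.12, -0.60 and -0.12 without old hets 1, 2 and 3. The ribosomal protein list did not pass without old het 1 (-0.17, adjusted p = 0.0752). The number of lists was 14 without old control 3 and 12 without old het 3. The gene count was 0 without any of the libraries but old control 2, without which it was 1.

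The log2 change of het against control differed between the ages in 9 genes, 8 with a higher signed value in old and 1 in young, by a test of the difference itself. This test includes the young controls, whose mitochondrial rRNA share was above that of every young het. Young controls 1 and 2 also differed from the young hets in sex-linked RNA. RNA quality, sex and genotype are thus not told apart in it. Slbp was 1.63 (SE 0.44) in old and -3.05 (SE 0.46) in young, a difference of 4.68 (SE 0.63, adjusted p = 0.00377). U3 was 0.67 (SE 0.39) and -3.28 (SE 0.41), a difference of 3.95 (SE 0.56, adjusted p = 0.00380). Cebpd was -0.79 (SE 0.67) in old mice, where both groups expressed it, against at least 26.8-fold higher in young het, and its fitted difference was -10.22 (adjusted p = 0.0228), or -5.53 with the young controls set at the floor. The others were the mitochondrial tRNAs mt-Tp (2.96) and mt-Tq (3.91), Snord49b (3.68), the spliceosomal RNA U1 (3.13), Cnot3 (3.09) and Prkacb (2.84), with adjusted p-values from 0.0228 to 0.0398.

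Among the lists, 6 passed camera for this difference, and none held with an estimated correlation. By fry 1 list passed, which was not among the 6. The neutrophil primary granule list had a median of -0.93 (camera adjusted p = 7.51e-05, adjusted p = 0.681 with an estimated correlation), and 5 of its 25 members passed when adjusted over the list alone, with Gfi1 at -3.57 and Cst7 at -2.90, which did not pass over all genes (adjusted p = 0.0813 and 0.116). The stem and multipotent progenitor list was at -1.08, oxidative phosphorylation at -0.51 and ribosomal proteins at -0.55 (camera adjusted p = 0.0372, 0.0200 and 0.0380, and adjusted p = 0.681 with an estimated correlation for each). The stem list did not pass without old control 1 (-0.20, adjusted p = 0.796), old het 2 (-0.98, adjusted p = 0.133), young control 1 (-0.94, adjusted p = 0.0669) or young het 3 (-0.83, adjusted p = 0.0568). Oxidative phosphorylation did not pass without old control 3, old het 3, young control 3 or young het 3 (adjusted p = 0.0539, 0.0646, 0.0514 and 0.0568), and was at -0.83 without old het 2. Ribosomal proteins did not pass without old control 3, old het 1, old het 3, young control 2, young control 3, young het 2 or young het 3 (adjusted p of up to 0.123), and were at -0.35 without young het 2. The primary granule list was at -0.51 without young het 1. The mitochondrial genome list was at 2.11, with 9 of 10 members higher when adjusted over the list alone (camera adjusted p = 1.27e-09, adjusted p = 0.551 with an estimated correlation), and mt-Nd4 was at 2.35. The sex-linked list passed as well, with Ddx3y at 10.90, or 8.50 with the young hets set at the floor, and a median of 8.62, or 6.60 with genes at 0 set at the floor (camera adjusted p = 7.10e-04, adjusted p = 0.492 with an estimated correlation). Over 10604 genes, which are not independent replicates, the log2 changes of the old and the young comparison had a Pearson's r of -0.143 and a Spearman's rho of -0.180, and the comparisons share no library. Pearson's r was -0.0723 without old het 1, -0.0863 without old het 3, -0.0747 without young het 2 and -0.0832 without young het 3. Of the 45 genes called in young, 10 had the same sign in old, and 0 genes were called in both. At an unadjusted p under 0.05, 94 genes were common to both comparisons, whatever their direction, where 53.3 would be with independent lists. Both comparisons used the same estimate of each gene's spread, so their lists are not independent and the excess does not show a shared effect.

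The count of 9 moved by more than 1.5 times without old control 1 (4), old control 3 (2), old het 1 (4), old het 2 (294), old het 3 (3), young control 2 (2), young control 3 (143), young het 1 (18), young het 2 (3) and young het 3 (2). It was 284 by DESeq2, 2 by limma-voom, 20 with Xist as a covariate and 1, a gene not among the 9, with the mitochondrial rRNA share as a covariate. With every library thinned to 645460 counts it was a median of 55 over 5 draws (43 to 63), with all 9 among them at the median, over 7926 tested genes. Without young het 3, 3 lists passed.

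Averaged over both ages, no gene passed in het against control (adjusted p of 0.520 or more). U3 was at -1.30 (SE 0.28, adjusted p = 0.520), Cebpd at 4.32 (SE 0.91), Hdc at 1.06 (SE 0.26) and F2r at -1.60 (SE 0.39), with Ddx3y leading by p (-5.82). With the groups at 0 counts set at the floor, Cebpd was at 1.98 and Ddx3y at -4.62. The count was 0 of 10604 with edgeR, with 615 genes at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma-voom, and it was 4 without young control 3. Camera called 7 lists, and 4 without old het 2 or young het 1. The primary granule list was at a median of 0.47, with Cst7 at 1.23 and Gfi1 at 1.06, the basophil and mast cell list at 0.51 and the unfolded protein response list at 0.23 (camera adjusted p = 3.46e-04, 0.00379 and 0.0341, and adjusted p = 0.661 with an estimated correlation for each). The megakaryocyte list was at -0.24, with Ctla2a at -2.10, the MHC class II list at -0.50, or -0.69 with genes at 0 set at the floor, and the mitochondrial genome list at -0.57 (camera adjusted p = 0.00617, 0.0341 and 3.58e-04, and adjusted p = 0.661 with an estimated correlation for each). The sex-linked list passed too, with a median of -4.68, or -3.50 with genes at 0 set at the floor (camera adjusted p = 1.02e-07, adjusted p = 0.0949 with an estimated correlation). When adjusted over the list alone, 0 primary granule, 1 basophil and 1 megakaryocyte member passed. The megakaryocyte list did not pass without old control 1 (0.00, adjusted p = 0.293), young control 3 (-0.20, adjusted p = 0.0752) or young het 1 (-0.19, adjusted p = 0.0890), and was at -0.39 without old het 3 and -0.44 without young het 2. The MHC class II list did not pass without old control 1 (-0.17, adjusted p = 0.591), old het 2, young control 3 or any 1 of the young hets (adjusted p from 0.0524 to 0.137). The unfolded protein response list did not pass without old control 1, old het 2, young control 1, young control 2 or young het 1 (adjusted p from 0.0713 to 0.293), and was at 0.35 without old control 2. Without old het 2 the primary granule (0.20, adjusted p = 0.128) and mitochondrial genome lists (-0.38, adjusted p = 0.190) did not pass, and without young control 1 the basophil list (0.40, adjusted p = 0.0555), which was at 0.76 without young control 3.

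Old and young control progenitors differed in the most genes, with 740 past the threshold. Camera called 11 lists, among them the primary granule, stem and interferon lists as higher and the erythroid, B lymphoid and mitochondrial genome lists as lower in old control, and none of them passed with an estimated correlation (adjusted p of 0.309 or more). Prtn3, a neutrophil serine protease, was 1995 ± 1080.1 CPM in old control and 424 ± 196 in young control (SD, n = 3 each; log2 2.23, SE 0.47, adjusted p = 0.00752). Pbx3, a HOX cofactor, was 59.5 ± 24.7 against 5.31 ± 2.61 (3.53, SE 0.60, adjusted p = 0.00181). Camp, a secondary granule peptide, was 385 ± 244 against 2754 ± 1264 (-2.84, SE 0.46, adjusted p = 0.00148), and Bax, a p53 target that promotes cell death, 52.8 ± 8.69 against 341 ± 79.3 (-2.69, SE 0.38, adjusted p = 8.80e-04). The groups did not overlap in these 4 genes.

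With edgeR, 740 of 10604 genes passed, 296 higher and 444 lower in old control, and in 714 of them the groups did not overlap. Over all tested genes the groups lay apart in 31.2%, where 10% would by chance. The median log2 change of all genes was 0.22. Genes with 0 counts in every young control included the class II gene H2-Eb1 (at least 40.4-fold higher in old control), the leukocyte tetraspanin Cd53 (33.7-fold), Cebpd (26.4-fold), Laptm4b (21-fold), the interferon-induced GTPase Gbp2 (18-fold) and Ms4a4b (14.4-fold), each of these folds being a lower limit. Their adjusted p-values lay between 0.00148 and 0.0459. Among the genes lower in old control were SNORD86 (-7.26), Tnf (-4.77), Speg (-4.46), Snora68 (-4.28) and Pax5, the B cell commitment factor (-4.27), with adjusted p-values between 9.39e-04 and 0.0173.

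In the primary granule list 9 of 25 members rose, and 13 rose and 1 fell when adjusted over the list alone, with a median of 1.34 (camera adjusted p = 1.96e-05, adjusted p = 0.469 with an estimated correlation). They included Gfi1 (2.83), Cst7 (3.36) and Gstm1 (2.45). In the stem and multipotent progenitor list 4 of 25 rose, and 8 rose and 1 fell when adjusted over the list alone, at a median of 1.24 (camera adjusted p = 0.00786, adjusted p = 0.553 with an estimated correlation). These 4 were Lmo2 (1.43), Hlf (3.33), Ly6e (1.67) and Meis1 (2.17). The megakaryocyte list had a median of 1.25 with 0 of 22 members past the threshold, also when adjusted over the list alone (camera adjusted p = 0.00786, adjusted p = 0.469 with an estimated correlation). In the interferon response list 6 of 42 rose, and 8 when adjusted over the list alone, at a median of 0.90 (camera adjusted p = 0.0159, adjusted p = 0.553 with an estimated correlation), with Psmb9 at 2.36, Ifi47 at 3.30 and Dtx3l at 1.83. Hlf was counted at 270.2 CPM in old control 1 and at 31.8 and 34.5 CPM in old controls 2 and 3, and Meis1 at 388, 44.3 and 37.1 CPM. With old control 1 left out, the stem, megakaryocyte and interferon lists were at 0.34, 0.63 and 0.48 and did not pass (adjusted p = 0.380, 0.124 and 0.291).

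The erythroid list was lower in old control at a median of -0.92, with 33 of 36 members negative and 3 of them past the threshold, or 4 when adjusted over the list alone (camera adjusted p = 6.52e-08, adjusted p = 0.469 with an estimated correlation). Alad (-1.55) and Fech (-1.92), enzymes of haem synthesis, and Zfpm1, the GATA1 cofactor FOG1 (-1.92), fell. In the B lymphoid list 4 of 15 fell, and 4 fell and 1 rose when adjusted over the list alone, at a median of -1.41 (camera adjusted p = 0.00786, adjusted p = 0.469 with an estimated correlation), among them Ebf1 (-3.37) and Vpreb1 (-2.43). The LK gate leaves out cells with lineage markers, and Pax5 was 35 ± 15.8 CPM in young control. In the mitochondrial genome list 9 of 10 fell, and 10 when adjusted over the list alone, at a median of -2.36 (camera adjusted p = 3.22e-14, adjusted p = 0.309 with an estimated correlation), with mt-Nd4 at -3.04, mt-Nd1 at -2.61 and mt-Cytb at -2.58. Mitochondrial rRNA was 2.07 ± 0.345% in old control and 5.87 ± 2.07% in young control. The replication list had a median of -0.15, with 2 of 48 members lower, also when adjusted over the list alone: Slbp (-4.19) and Dut, which clears dUTP (-2.23) (camera adjusted p = 0.0480, adjusted p = 0.469 with an estimated correlation). The replication list did not pass without old control 1 (-0.03, adjusted p = 0.316), young control 1 (-0.20, adjusted p = 0.0568) or young control 3 (-0.23, adjusted p = 0.0554), and was at -0.27, -0.23 and -0.35 without old control 2, old control 3 and young control 2. The B lymphoid list did not pass without old control 2 (-0.80, adjusted p = 0.119), and the erythroid list was at -0.61 without old control 2 and -1.63 without old control 3.

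Metabolic lists passed with small medians. Glycolysis and hypoxia was at 0.47, with 2 of 27 members higher and 1 lower, and 3 and 1 when adjusted over the list alone (camera adjusted p = 0.0268, adjusted p = 0.309 with an estimated correlation, fry adjusted p = 4.09e-04). Ndrg1 (2.01) and Pdk1 (1.73) rose and Vegfa (-1.59) fell. Oxidative phosphorylation was at 0.56 with 1 of 73 members higher, also when adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.574 with an estimated correlation), the succinate dehydrogenase subunit Sdha (1.45). Ribosomal proteins were at 0.55, with 2 of 70 higher, Rps18 (1.53) and Rps10 (1.10), and 3 lower, among them Rpl6 (-2.80) and Rpsa (-1.34), or 5 and 4 when adjusted over the list alone (camera adjusted p = 0.0420, adjusted p = 0.469 with an estimated correlation). The ribosomal protein list did not pass without old control 1, old control 3, young control 2 or young control 3 (adjusted p = 0.0692, 0.0692, 0.147 and 0.0803). Oxidative phosphorylation did not pass without old control 3 (0.50, adjusted p = 0.153), young control 2 (0.44, adjusted p = 0.0828) or young control 3 (0.35, adjusted p = 0.0915). Glycolysis and hypoxia did not pass without young control 1 (0.44, adjusted p = 0.0735) or young control 2 (0.38, adjusted p = 0.119), and was at 0.80 without young control 3. Reads of ribosomal protein genes can be shared with their pseudogenes, which makes single members uncertain.

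Members also moved in lists that did not pass camera. In the immediate early and dissociation stress list 4 of 24 fell, Nfkbia (-2.41), Jund (-2.24), Zfp36 (-2.30) and Fos (-1.73), and 1 rose beside 4 that fell when adjusted over the list alone (median -0.02, camera adjusted p = 0.195). In the ribosome biogenesis list 6 of 47 fell, among them Wdr12 (-1.96) and the nucleolar protein Npm1 (-2.19), and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.203). The chaperones Hsp90aa1 (-1.57) and Hsp90b1 (-1.93) were among 3 of 29 in the heat shock list that fell, also when adjusted over the list alone (camera adjusted p = 0.125). In the MHC class II list 4 of 14 rose, with H2-Aa at 4.39 and H2-DMb1 at 1.94, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0846). In old het against old control the median of this list went from -1.38 to -0.07 without old control 1. The size of the rise of its members, H2-Eb1 included, can thus rest in part on that library. In the secondary granule list 2 of 15 fell, Camp and Cybb (-1.51), also when adjusted over the list alone (camera adjusted p = 0.0846). Monocyte markers moved both ways, with 3 of 22 higher, such as Slpi (3.99), and 2 lower, Itgam (-3.43) and F13a1 (-1.69), or 6 and 3 when adjusted over the list alone (camera adjusted p = 0.398). Idh1 (3.29) and the DNA methyltransferase Dnmt3b (1.58) were the 2 of 47 chromatin regulators that rose, also when adjusted over the list alone (camera adjusted p = 0.913). Ccnd1 (3.62) was the 1 of 19 Wnt list members that passed, against 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.451). In the unfolded protein response list Xbp1 (1.74) and Hyou1 (1.90) rose and Hsp90b1 fell, the same counts of 2 and 1 being reached when adjusted over the list alone (camera adjusted p = 0.121). Of the T and NK list Cd27 (2.79) and Ms4a4b rose among 8 members, and 3 when adjusted over the list alone, with a median of 2.09 or 1.83 with genes at 0 set at the floor (camera adjusted p = 0.121).

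A single member passed in the basophil list, Prss34 (3.0), beside Hdc at 1.21 (adjusted p = 0.0540), and 4 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.748). Vim (1.17) was the 1 of 7 stromal and endothelial genes that rose, or 4 when adjusted over the list alone (camera adjusted p = 0.0581, fry adjusted p = 0.0423). Nuf2 (-1.19) of the 50 mitosis genes fell, or 0 when adjusted over the list alone (camera adjusted p = 0.913), and Mvk (-1.82) of the 23 cholesterol genes, or 2 when adjusted over the list alone (camera adjusted p = 0.828). Pbx3, Meis1 and Lmo2 rose and Npm1 fell among 31 genes of the leukaemia and HOX list, also when adjusted over the list alone (camera adjusted p = 0.349). Among 23 published WT1 target genes, 2 rose, Gfi1 among them, and 3 fell, with Vegfa and Hsp90aa1, also when adjusted over the list alone (median -0.58, camera adjusted p = 0.203). Bax fell and 1 other gene rose among 24 p53 targets, also when adjusted over the list alone (median -0.18 against a mean of 0.10, camera adjusted p = 0.657). Tnf and Nfkbia were the 2 of 17 TNF and NF-kB genes that fell, also when adjusted over the list alone, while the list median was 0.54 and the camera test pointed lower (camera adjusted p = 0.770). No member passed among 16 quiescence genes (median 0.89, camera adjusted p = 0.0624, fry adjusted p = 0.0348) or 61 DNA repair genes (median -0.01, camera adjusted p = 0.752), also when adjusted over the list alone. Xist was at -9.13, from young control 3 alone, and the sex-linked list had a median of 0.49 and a mean of -1.23 (camera adjusted p = 0.701).

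The count of 740 fell to 315, 335 and 394 without old control 1, 2 and 3, and to 432 and 472 without young control 1 and 2, while it was 777 without young control 3, with 521 of the calls shared. It was 1321 by DESeq2, 386 with Xist as a covariate, 463 without old control 1 and young control 3, and 6 with the mitochondrial rRNA share as a covariate, a share that separates all 3 old from all 3 young controls.

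Between old and young het progenitors, the gene that passed was Fos. Camera called 5 lists, with the erythroid, neutrophil secondary granule and immediate early lists lower in old het, and none passed with an estimated correlation (adjusted p of 0.128 or more). Fos was 3.73 ± 1.21 CPM in old het and 57.9 ± 19.3 in young het (SD, n = 3 each), a log2 change of -3.90 (SE 0.59, adjusted p = 0.0176), without overlap of the groups. Camp was 293 ± 78.3 against 1829 ± 841 (-2.64, SE 0.46, adjusted p = 0.0656). The next genes by p, which did not pass, included the receptor Cd300lf (-2.17), the glutaredoxin Glrx (-2.49), Gng11 (2.12), the minor spliceosomal RNA U4atac (2.62) and the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y, which had 0 counts in every young het and in old het 1. Against these zeros the old het means were at least 499-fold, 253-fold, 98.1-fold and 80.3-fold higher.

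All 36 tested members of the erythroid list were lower in old het, at a median of -1.04, and 5 passed when adjusted over the list alone (camera adjusted p = 2.54e-14, adjusted p = 0.213 with an estimated correlation). The haem enzyme Alad was at -1.20, the erythropoietin receptor Epor at -2.31 and the iron carrier Slc25a37 at -1.33. The secondary granule list had a median of -0.93 over 15 members, 3 lower when adjusted over the list alone (camera adjusted p = 2.97e-07, adjusted p = 0.213 with an estimated correlation), with Ngp at -2.16, S100a9 at -1.57 and Cybb at -0.93. The immediate early and dissociation stress list had a median of -0.54 over 24 members, 8 lower when adjusted over the list alone (camera adjusted p = 4.96e-07, adjusted p = 0.128 with an estimated correlation), with Zfp36 at -2.42 and the phosphatase Dusp1 at -2.14. The Wnt list was higher, at 0.25 over 19 members, 3 of them when adjusted over the list alone (camera adjusted p = 0.0359, adjusted p = 0.180 with an estimated correlation, fry adjusted p = 0.0197), with the cyclins Ccnd1 at 2.06 and Ccnd2 at 1.17. The sex-linked list passed with a median of 9.04, or 6.62 with genes at 0 set at the floor (camera adjusted p = 1.01e-05, adjusted p = 0.128 with an estimated correlation), as 2 of 3 old hets and none of the young hets carried Y-linked RNA. The count of 1 gene became 5 without old het 1, 4 without young het 1 and 0 without any of the other 4 libraries, and it was 25 by DESeq2, 1 by limma-voom, a gene other than Fos (Fos -3.82, adjusted p = 0.442), and 0 with Xist as a covariate, where Fos was at -3.35 (adjusted p = 0.938). Without old het 2 or old het 3, 8 lists passed. The Wnt list did not pass without old het 1 (0.22, adjusted p = 0.0629), young het 1 (0.36, adjusted p = 0.0951) or young het 3 (0.22, adjusted p = 0.137). Without old het 2 it was at 0.42, the secondary granule list at -1.45 and the immediate early list at -0.85.

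**Figure D4:**
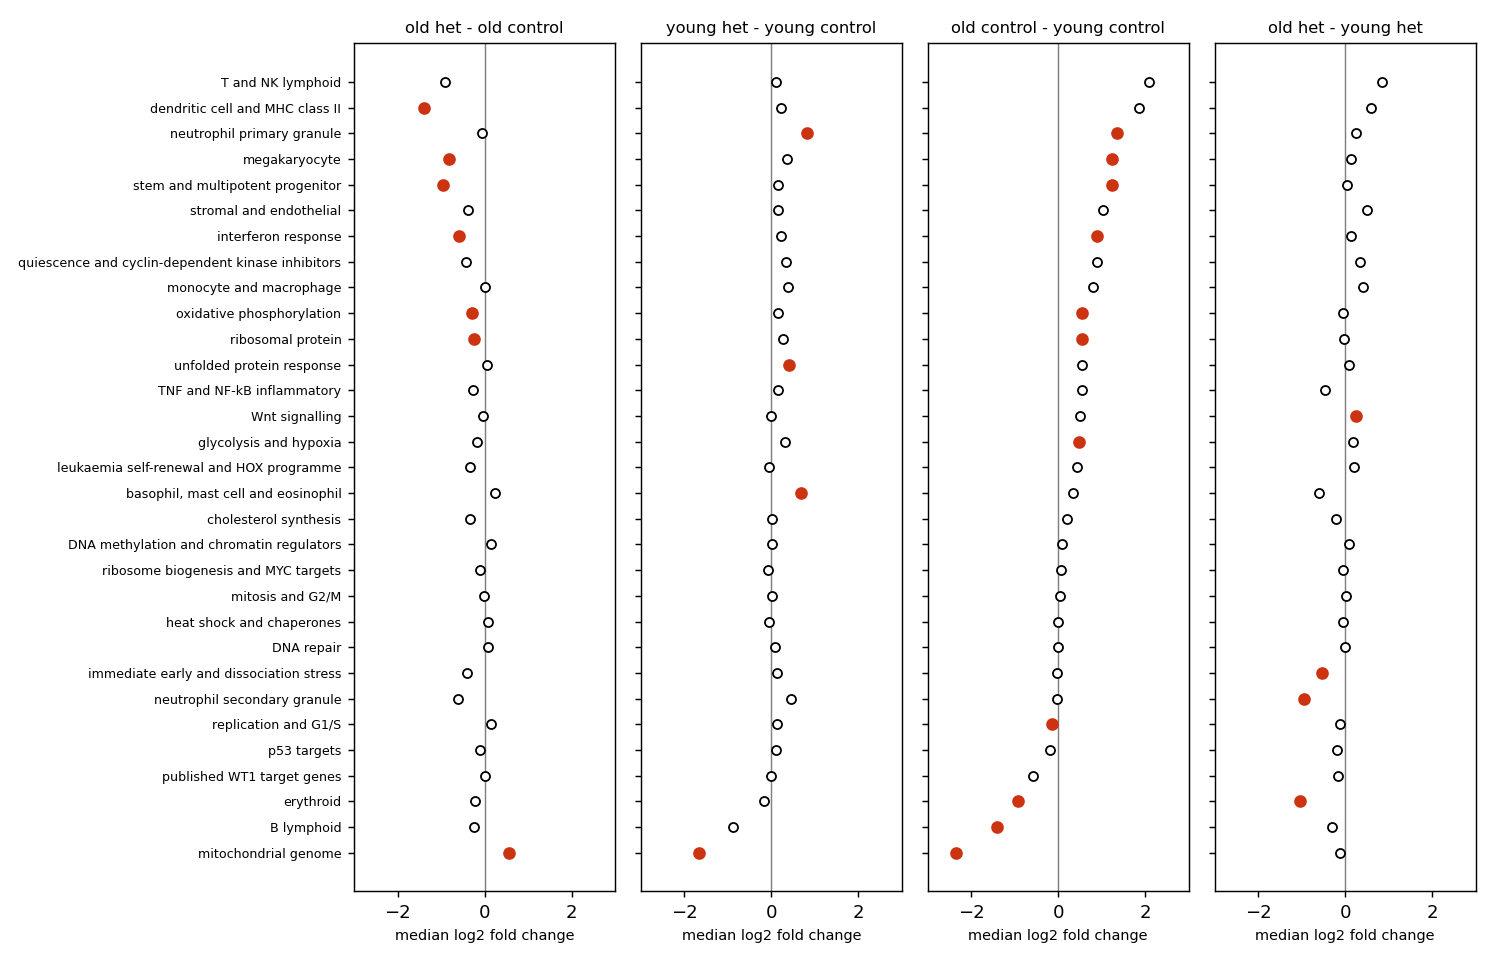
Median log2 fold change of 31 gene lists in 4 comparisons, with filled red points where camera passed an adjusted p of 0.05 and open points otherwise. None of the filled points passed with an estimated correlation, and the mitochondrial genome list has the lowest median among controls, at -2.36.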

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

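The tests of sex, of old control 1 and of Fos, and the bounds for the counts of sample splits, were chosen only after the result was seen; the tests of RNA quality and depth on the young controls were not.

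The log2 change of het against control differed between old and young in 9 genes by a test of the difference itself. As old minus young log2 these were Slbp 4.68, U3 3.95, mt-Tp 2.96, Cnot3 3.09, Cebpd -10.22 (-5.53 with the young controls at the floor), mt-Tq 3.91, Snord49b 3.68, U1 3.13 and Prkacb 2.84. Camera called 6 lists at its preset correlation and none with an estimated one (adjusted p of 0.492 or more), with medians of: stem and multipotent progenitor -1.08, neutrophil primary granule -0.93, oxidative phosphorylation -0.51, ribosomal protein -0.55, mitochondrial genome 2.11 and sex-linked 8.62 (6.60 at the floor). Of 100 drawn splits of the samples, 2 gave as many as 9 genes, the real one included. That share lies under 0.05, but the bound was chosen after the result was seen and was not corrected for the other counts tested. Chance was therefore not excluded. With the mitochondrial rRNA share as a covariate 1 gene was called and 0 of the 9 were kept. Without mitochondrial, small RNA, sex-linked and predicted genes 3 were called, all of them among the 9. That fit leaves out mt-Tp, mt-Tq, U3, U1 and Snord49b from the start, so their absence from its calls carries no information. The 3 calls came from Slbp, Cnot3, Cebpd and Prkacb, the genes of the 9 that it could test. RNA quality stays open for these 9 genes. The other of these 2 splits gave 112 genes, with old control 1 and 3, old het 2, young control 1 and 2 and young het 1 on the same side. It parted the libraries of each age on the second principal component without overlap. The old libraries lay at 17.2 or above against 13.1 or below, and the young at -38.8 or below against 17.6 or above. Why this split gave more genes than the real one was not tested. For the lists 48 of 100 splits gave 6 or more, with a highest other of 13, so chance was not excluded.

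Young controls stood apart from young hets and old controls, with 45 and 740 genes. Thinning every library to 645460 counts kept a median of 608 of the 740 genes over 5 draws (597 to 644), which argues against depth as the whole cause. Without young control 3, 777 genes were called, 521 of them among the 740. This argues against sex-linked differences of that library as the cause of those 521, and the question stays open for the rest of the 740. Leaving out a library that lay apart also changes the spread, so the count of 777 itself decides nothing. Xist as a covariate kept 380 of the 740 (386 called). A gradient of RNA quality stays open. The slope on the mitochondrial rRNA share within the groups not compared had the matching sign in 88.1% of 724 genes of the old against young control comparison (12 of 36 arrangements of the libraries as large, permutation p = 0.333) and in 83.8% of 37 genes of the young comparison (8 of 36, permutation p = 0.222), where the smallest possible p was 0.0278. An effect of age or genotype cannot be told apart from it, since the share separates the compared groups, and sex stays open for the 45 genes, which became 157 without young control 3 and 21 with Xist as a covariate, 10 of them shared.

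Lists of stem, megakaryocyte, MHC class II and interferon genes were lower in old het than in old control by camera at its preset correlation, and none of them with an estimated one (adjusted p = 0.611 each). Without old control 1 the smallest adjusted p of these 4 lists was 0.0767 by camera, with medians of -0.03, -0.33, -0.07 and -0.07, which is consistent with that library as the source of the 4 calls. Oxidative phosphorylation and ribosomal protein lists kept their calls at the preset correlation without it (largest adjusted p = 0.0219, medians -0.28 and -0.22), which argues against it for these, although the first lost its call without old control 3 and the second without old het 1. Why old control 1 holds more stem cell and class II RNA was not tested, and a het effect on the lists that were kept stays open.

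Fos was lower in old het than in young het. With the mitochondrial rRNA share as a covariate its log2 change was -3.99 (SE 0.57, edgeR adjusted p = 0.0136). The mean share on the log scale was 3.17% in both groups (log2 difference 0.00137, SE 0.593), so this fit could not move the fold much. Equal means argue against a straight-line gradient in this share as the cause, and RNA quality that the share does not track stays open. The call was not made by limma-voom (log2 -3.82, adjusted p = 0.442). With Xist as a covariate it was -3.35 (SE 0.80, adjusted p = 0.938) against -3.90 (SE 0.59), so the fold was largely kept and the call ended with the larger error, and sex stays open. An effect of age was not tested apart from these. Cell handling was not tested either, although Fos belongs to the immediate early and dissociation stress list.

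For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. In genes, the real split gave 0 in old het against control, 45 in young, 740 in old against young control and 1 in old against young het, with a highest other of 0 in each, and 10, 1, 1 and 1 splits were as large. In lists, the real values were 7, 5, 11 and 5, the highest others 17, 5, 14 and 5, and 10, 3, 3 and 4 splits were as large. No split of the old het and old control libraries gave fewer than the real 7 lists, so that number does not set the groups apart. For the average over both ages, 100 of 100 drawn splits gave as many genes as the real 0 and 39 as many lists as the real 7, so chance was not excluded. The highest others were 126 genes and 13 lists, and the split with 126 genes set old control 1 and old hets 1 and 3 with the young controls. Why it gave so many genes was not tested.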

How the results depend on the processing

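The mitochondrial rRNA covariate, the fit without RNA classes (mitochondrial, small RNA, sex-linked and predicted genes) and the fit without old control 1 and young control 3 were chosen only after the results were seen. Over 3048 values of named genes under 23 settings, 3042 kept their direction and 2310 also their side of the threshold, with 624 weaker and 108 stronger. Of 611 values of lists, 609 kept their direction, 433 were the same and 176 weaker. The genes were named by rules that favour small p-values and groups without overlap, and the lists by their call in the main fit. A reversal was thus unlikely from the start, and the kept directions do not measure how firm the results are. The cause of a change was not tested unless stated.

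DESeq2 gave 356 genes for young, 284 for the difference, 3 for the average, 1321 for age in controls and 25 for age in hets, and limma-voom gave 23 for young and 2 for the difference. Without a low-count filter there were 11 genes for old, 258 for young, 216 for the difference, 23 for the average and 22 for age in hets. The compared groups alone gave 13 for young and 2 for age in hets. With Xist as a covariate there were 21 for young, 20 for the difference, 386 for age in controls and 0 for age in hets. With the mitochondrial rRNA share as a covariate there were 2 for young, 1 for the difference, 6 for age in controls and 2 for age in hets. Without the RNA classes there were 7 for young, 3 for the difference and 2 for age in hets. Without old control 1 and young control 3 there were 241 for young, 59 for the difference, 2 for the average, 463 for age in controls and 8 for age in hets.

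Leaving out 1 library gave 0 to 1 genes for old, 1 to 157 for young, 2 to 294 for the difference, 0 to 4 for the average, 315 to 777 for age in controls and 0 to 5 for age in hets. It gave 4 to 14 lists for old, 3 to 6 for young, 3 to 9 for the difference, 4 to 10 for the average, 8 to 14 for age in controls and 4 to 8 for age in hets. Each library that moved a count by over 1.5 times is named with the comparison.

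With an estimated correlation camera called 0 lists in every comparison. By fry there were 0 for old, 1 for young, 1 for the difference, 0 for the average, 6 for age in controls and 1 for age in hets. Lists numbered 4 for old and 2 for the difference with the mitochondrial rRNA covariate, 4 for old without old control 1 and young control 3, and 10 for the difference without a filter.

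These values reversed. For Xist, old het against old control, the log2 change was -0.0832 with Xist as a covariate, and from -4.76 without old het 1 to 8.88 without old het 3. For Meis1, old het against old control, it was 0.25 without old control 1 and young control 3, and from -2.15 to 0.25 without single libraries, the last without old control 1. For mt-Rnr2, old het against old control, it was -0.0403 and for the mitochondrial genome list, old het against old control, the median was -0.0850, both with the mitochondrial rRNA covariate. For Kdm5d, old het against young het, it was -0.14 with Xist as a covariate. Where Xist or mitochondrial RNA was the covariate, the fit removes that gene's or list's own signal by construction. For the oxidative phosphorylation list, old control against young control, the test turned with the mitochondrial rRNA covariate, at a median of 0.0385. The correlation of het effects in old and young ran from -0.155 to -0.0723 without single libraries, and was -0.150 with the stricter filter and -0.117 with limma-voom. Other scalings moved the median of all genes by under 0.1. No paired analysis was possible because each number in the labels occurs once, and the replicate numbers used here only name the samples. At the least depth of 645460 counts, in young control 2, 3 counts are 4.65 CPM, against 1.87 CPM in young control 1 and 2.20 CPM in young control 3, so that lower levels in a single library rest on under 3 counts.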

Other observations

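Several lists without a call in het against control had medians away from 0. B lymphoid genes had a median log2 change of -0.88 in the young comparison, with 11 of 15 members negative and 0 past the threshold, also when adjusted over the list alone (camera adjusted p = 0.104). T and NK genes had a median of -0.92 over 8 members in the old comparison (camera adjusted p = 0.212), and secondary granule genes -0.62 over 15 (camera adjusted p = 0.212). In the young comparison, 2 of 31 leukaemia and HOX genes were higher and 3 lower when adjusted over the list alone, against 0 over all genes, with a median of -0.06 (camera adjusted p = 0.685).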
